A study of Homo sapiens with 6 samples.

How the data were processed

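The series holds 6 iCLIP libraries from BEAS2B, an established line of human bronchial epithelial cells. iCLIP (individual-nucleotide crosslinking and immunoprecipitation) fixes protein to RNA with ultraviolet light, recovers the protein with an antibody and sequences cDNAs that stop beside the crosslinked nucleotide. Per the labels, 3 libraries were made with an antibody against QKI-5, the nuclear form of the RNA-binding protein Quaking, and 3 control libraries were made without antibody. Both groups carry the replicate numbers 1 to 3. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

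Each deposited file lists single-nucleotide crosslink positions on one strand, with a whole-number count of crosslink events at each position. The deposited counts are not normalized and each file holds 1 library. Per the submitters' processing notes, cutadapt, Bowtie and the build hg19 were used, and their versions are not given in the sources used here. Per the labels' protocols, reverse transcription used a primer with barcodes. Whether reads that were PCR copies of one cDNA were merged by barcode before the authors counted events, and how reads with several alignments were placed, is not given in the sources used here. Without that knowledge, intervals and floors below cover counting error only. All coordinates are hg19, counted from 1.

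No hg19 genome or gene annotation was used here. Positions were therefore not assigned to genes, exons, introns or UTRs, and counts were summed over strand-specific 10 kb windows, as fixed before the data were examined for this case. The planned shares by transcript region, the search for the QKI recognition element, the hexamer ranking, the position around splice sites and the tests of 12 gene lists, cell type markers included, all need that annotation and were not run. The planned values for QKI, ADD3 and NUMB are not reported for the same reason.

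EPM are events per 1000000 events of the library. The floor is 3 events, over one library or over the pooled group as stated. Library totals were compared by a two-sided exact permutation test, whose smallest possible p with 3 libraries against 3 is 0.1. This test, here and wherever it is used below, does not use the replicate numbers as pairs. A paired permutation of 3 pairs could not reach so small a p. Windows were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1) on event counts, with TMM factors, the filterByExpr filter and the group as the only term. This left 29960 of 174732 windows with any event. Windows with an adjusted p (Benjamini-Hochberg) under 0.05 were called higher or lower. Log2 fold changes are QKI-5 over control, at the default prior count of the edgeR fit. A prior count of 2 was used only in the check of same-numbered libraries below. Fold changes of windows with few or no control events are therefore little shrunken. Log2 fold changes carry the TMM factors and EPM do not, so they differ from the ratio of the printed EPM. On simulated counts for 26863 windows with a dispersion of 0.04, the test recovered 100% of 50 windows raised 16-fold and 36% of 50 raised 4-fold. It recovered 75% of 16 windows lowered to 0.0625 of the control and 12.5% of 16 lowered to 0.25, and called 1 of 26731 unchanged windows. The simulated counts held no copied events, no effect of the replicate number and no difference in scaling between libraries. These rates may therefore not hold for the deposited libraries.

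Significant crosslink sites were called in each library by comparing the events within 3 nt of a position with 100 random redistributions of the window's events, at a false discovery rate under 0.05. Sites within 15 nt were merged to clusters, and a cluster found in at least 2 of the 3 QKI-5 libraries is called reproducible. On simulated data with 4000 windows and 200 planted sites of 12 events, all planted sites were recovered (100%), and 0.0114% of other positions were called when events were independent. When events at one position were copies of each other, 10.3% of other positions were called. Counting each position once lowered that to 0.0156% and recovered 99.5% of planted sites. Counting each position once was added after the data were seen, because of the repeated events described in the report. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 was used for these steps.

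The rule for named items was fixed before the data were examined and applied to windows in place of genes. It takes the 10 higher windows with the smallest adjusted p whose EPM in each QKI-5 library is above that in each control, the 6 lower windows by the reversed rule, the 8 windows with the most reproducible clusters, and the 5 reproducible clusters with the highest geometric mean EPM over the QKI-5 libraries. The 20 windows with the largest mean control share, the clusters outside them and the held-out clusters were chosen after the data were seen. The alternatives for windows were other normalizations, no filter, distinct positions, thinning, leaving out each library, the DESeq2 1.42.0 Wald test and the replicate number as a block. Each fit without a library set its filter and TMM factors anew, so its fold changes also carry a change of scaling. Distinct positions cannot exceed the window length, so that alternative lowers dense windows in deep libraries.

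Whether same-numbered libraries deviate together was checked by correlating their deviations from the group means. Over all 29960 tested windows, same-numbered pairs had r = 0.0012, 0.105 and 0.0717. Most of these windows hold very few control events. Over the 121 windows with a mean of at least 10 control events the same pairs had r = 0.192, 0.498 and 0.388, and each library correlated best with its own number. The labels do not say what a number marks. The numbers were taken as pairing the libraries on the second set, and the blocked value is printed beside the window result.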

Results

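QKI-5 is a nuclear RNA-binding protein that regulates splicing, and the series mapped its contacts with RNA in BEAS2B bronchial epithelial cells. The data are positions of crosslink events on hg19 in 3 QKI-5 iCLIP libraries and 3 libraries made without antibody. The QKI-5 libraries held 7283982, 2143279 and 2889146 events at 5239862, 1243745 and 1651104 positions for replicates 1, 2 and 3. The controls held 137926, 41475 and 29810 events at 105833, 25736 and 18372 positions. One event is 7.25 EPM (events per 1000000 events of the library) in control replicate 1, and 3 events are 21.8, 72.3 and 101 EPM in the 3 controls, against 0.412, 1.40 and 1.04 EPM in the QKI-5 libraries. Low control values are therefore coarse.

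The first comparison asked how much RNA crosslinked to protein was recovered with the antibody and without it. The mean total was 4105469 ± 2777821 events with the QKI-5 antibody and 69737 ± 59341 without it (SD, n = 3 each), a ratio of 58.9. Every QKI-5 library exceeded every control (two-sided exact permutation p = 0.1, unpaired, the smallest this test allows). By replicate number the ratio was 52.8, 51.7 and 96.9. Distinct positions gave a ratio of 54.3. Without control replicate 1 the ratio was 115 and without QKI-5 replicate 1 it was 36.1. Totals also depend on how deeply each library was sequenced, which the counts do not separate from recovery.

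Events repeated at one position were common where no other position lay within 100 nt. Of such isolated positions, 8.16% (95% exact binomial interval 7.98 to 8.34) carried more than 1 event in control replicate 1, 24.2% (23.6 to 24.7) in control replicate 2 and 34.7% (33.9 to 35.4) in control replicate 3. In the QKI-5 libraries the shares were 13.0% (12.9 to 13.1), 34.3% (34.2 to 34.4) and 40.5% (40.3 to 40.6) for replicates 1, 2 and 3. Within each replicate number the QKI-5 share was the higher one, by 4.83, 10.1 and 5.78 percentage points, while libraries of one group differed by more than that.

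**Figure D1:**
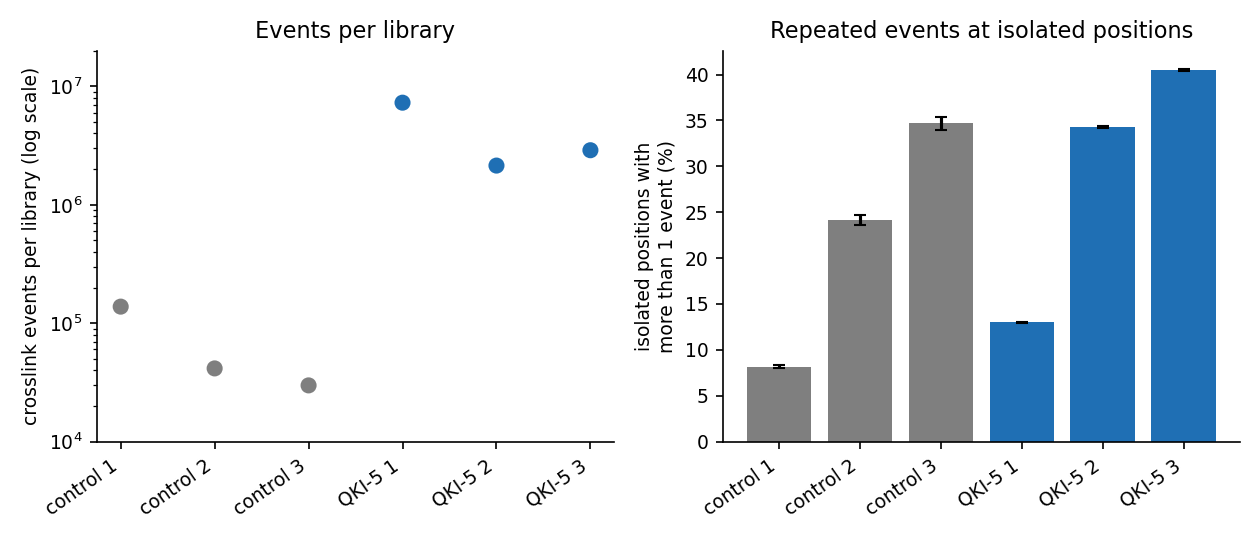
Left, crosslink events per library on a log axis for 3 controls without antibody (grey) and 3 QKI-5 iCLIP libraries (blue); right, the percentage of isolated positions with more than 1 event, with 95% exact binomial intervals. The QKI-5 totals lie between 2143279 and 7283982 and the control totals between 29810 and 137926, while the percentage of repeated positions ranges from 8.16 to 34.7 in controls and from 13.0 to 40.5 in QKI-5 libraries.

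The second comparison asked which genomic windows took a larger or smaller part of the events with the antibody. Of 29960 strand-specific 10 kb windows, 226 were higher and 32 were lower in QKI-5 iCLIP than in control (edgeR quasi-likelihood test, adjusted p under 0.05). With the replicate number as a block, edgeR called 0 higher and 0 lower, at a smallest adjusted p of 0.2, while 2195 windows had an unadjusted p under 0.05 and the DESeq2 Wald test without the block called 431 higher and 150 lower. None of the called windows named below keeps its call in that blocked fit, and their adjusted p values are from the fit without it, while their log2 fold changes differed by -0.05 to 0.42 between the fits (blocked minus unblocked). The higher windows had a median of 82.5 EPM in QKI-5 libraries and 11.2 EPM in controls, and all 226 held a reproducible QKI-5 cluster, as did 25 of the 32 lower windows and 27786 windows in all. The 62 higher windows without any control event and the 74 with 1 to 3 control events have fold changes set largely by counting. The lower windows had a median of 16.4 EPM in QKI-5 libraries and 134 EPM in controls. Joining called windows less than 50 kb apart gave 219 higher loci, of which 212 were single windows.

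Among the higher windows, the smallest adjusted p belonged to chromosome 10, minus strand, 13760001 to 13770000. It held 210 ± 61.6 EPM in QKI-5 libraries (SD, n = 3) and 21.6 ± 13.3 EPM in controls, a log2 fold change of 4.42 (SE 0.82, adjusted p = 3.5e-04 by edgeR), with 1 event in each control. The pooled ratio from these 3 control events was 15.9 (95% exact interval 5.43 to 77.1). With library totals, the scale of EPM, the log2 fold change of this window was 3.84. On chromosome 17, minus strand, 42540001 to 42550000 held 252 ± 24.03 EPM against 20.8 ± 18.2 EPM and contained 23 reproducible clusters. On chromosome 3, the plus-strand window 58110001 to 58120000 held the most QKI-5 signal of the 10, 378 ± 49.1 EPM against 73.6 ± 81.5 EPM in controls. The minus-strand window 56650001 to 56660000 of the same chromosome held 189 ± 19.3 EPM against 24.8 ± 36.8 EPM, with a pooled ratio of 13.5 (4.62 to 65.6) from 3 control events. With 1 library left out, the log2 fold change of the chromosome 10 window lay between 3.59 (without QKI-5 replicate 1) and 4.90 (without control replicate 3), and that of the chromosome 17 window between 3.21 (without QKI-5 replicate 3) and 5.68 (without control replicate 1). Those of the chromosome 3 windows lay between 2.64 (without QKI-5 replicate 2) and 4.45 (without control replicate 3) on the plus strand, and between 3.51 (without QKI-5 replicate 3) and 5.74 (without control replicate 3) on the minus strand.

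Another 3 of the higher windows lay on chromosome 5 (minus strand, 139640001 to 139650000), chromosome 14 (plus strand, 104140001 to 104150000) and chromosome 11 (minus strand, 47560001 to 47570000). They held 247 ± 22.6, 275 ± 15.5 and 189 ± 4.07 EPM in QKI-5 libraries, against 45.6 ± 51.0, 29.8 ± 33.0 and 20.1 ± 18.5 EPM in controls. Their log2 fold changes were 3.27 (SE 0.67), 3.15 (SE 0.65) and 3.31 (SE 0.71). Without control replicate 1 they were 4.08, 5.81 and 5.27, without QKI-5 replicate 2 they were 2.59, 2.44 and 2.60, and the other libraries left out in turn gave values between these. These values also carry the changed scaling of each fit. The chromosome 11 window held 193, 189 and 185 EPM in QKI-5 replicates 1, 2 and 3. Its log2 fold change fell to 2.74, 2.60 and 2.64 without each of them, so that fall does not rest on 1 of them. With distinct positions in place of events, all 3 lost their call, as did the plus-strand window on chromosome 3. The remaining 3 had almost no control events. On chromosome 13, plus strand, 42880001 to 42890000 held 74.1 ± 5.75 EPM and no control event, and was at least 5.35-fold higher against a floor of 3 events over the pooled controls. On chromosome 2, minus strand, 63670001 to 63680000 held 96.7 ± 24.2 EPM with 1 control event, a pooled ratio of 21.2 with an exact interval of 3.79 to 837. On chromosome 9, minus strand, 95470001 to 95480000 held 115 ± 9.57 EPM with 2 control events, a pooled ratio of 11.7 (3.22 to 96.3). The control events of the windows on chromosomes 2 and 9 came from 1 library each, control replicate 2 and control replicate 1, and without it no control event is left.

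The 6 named lower windows carried control events in every control library and 45 to 48 control events each. On chromosome 3, plus strand, 39440001 to 39450000 held 15.8 ± 2.99 EPM in QKI-5 libraries and 281 ± 118 EPM in controls, a log2 fold change of -3.25 (SE 0.44, adjusted p = 6.2e-09 by edgeR). With library totals that log2 fold change was -3.95. On chromosome 5, plus strand, 111490001 to 111500000 held 16.9 ± 11.8 against 191 ± 78.6 EPM. On chromosome X, minus strand, 118920001 to 118930000 held 18.8 ± 2.19 against 210 ± 97.7 EPM. On chromosome 11, plus strand, 8700001 to 8710000 held 26.2 ± 8.88 against 204 ± 90.1 EPM. On chromosome 6, plus strand, 133130001 to 133140000 held 33.2 ± 7.88 against 211 ± 107 EPM, and on chromosome 1, minus strand, 28900001 to 28910000 held 33.0 ± 12.3 against 204 ± 51.3 EPM. Without control replicate 1 the log2 fold changes on chromosomes 5, 11, 6 and 1 were -1.96, -1.41, -1.23 and -0.96 and no longer passed, and on chromosome X it was -1.96. Scaling changed in that fit too. The chromosome 1 window held 232, 145 and 235 EPM in controls 1, 2 and 3, so control replicate 1 did not stand apart there. Without control replicate 2 that on chromosome 6 was -1.79 and no longer passed. Without QKI-5 replicate 2 the log2 fold changes on chromosomes 3, 5, X, 11, 6 and 1 were -4.10, -4.38, -3.79, -3.56, -2.99 and -3.15. Without QKI-5 replicate 1 or 3 that on chromosome 3 was -3.76 and -4.11, that on chromosome X -3.54 and -3.60, that on chromosome 6 -2.72 and -2.65, and that on chromosome 11 without QKI-5 replicate 3 -3.11. With no filter on low counts the windows on chromosomes 6 and 1 lost their call. All 16 named windows kept the direction of their fold change under each alternative that gave them a value.

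**Figure D2:**
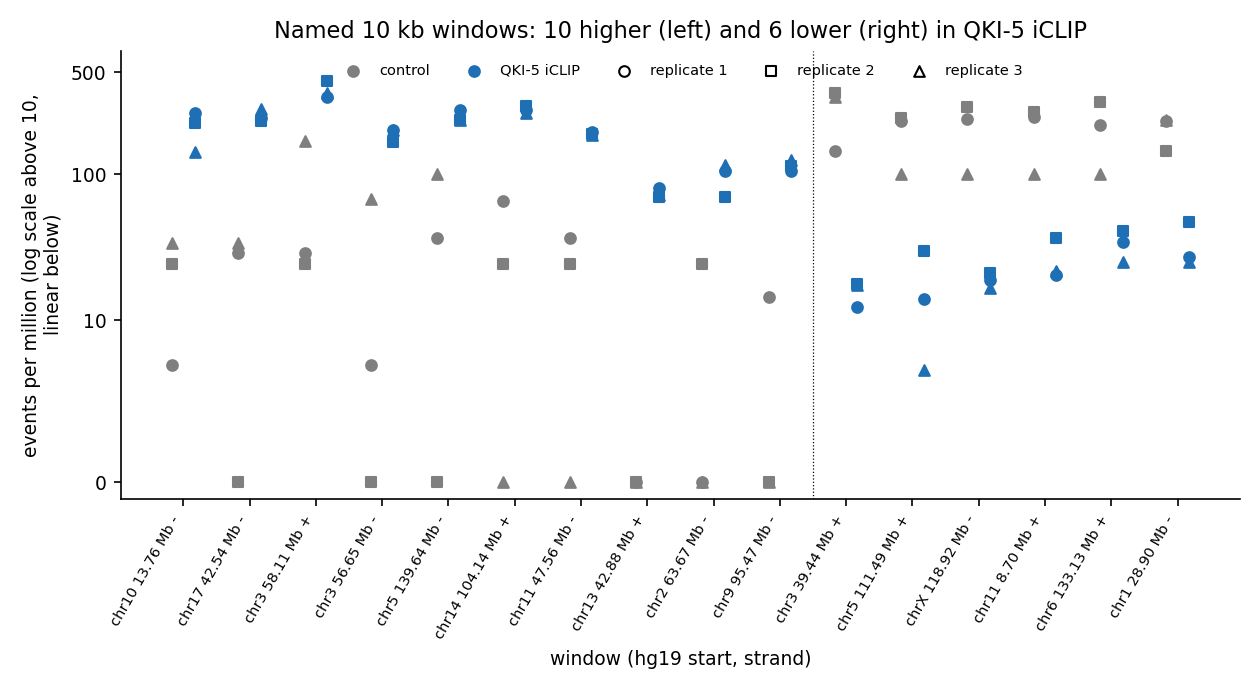
Events per 1000000 (EPM) in each library (symbols mark the replicate number) for the 10 higher and 6 lower named windows, on an axis that is linear below 10 and logarithmic above, with controls in grey and QKI-5 iCLIP in blue. In each window the 3 QKI-5 values lie on one side of the 3 control values, which the rule that chose the windows requires. Over all calls this held for 204 of 226 higher and 21 of 32 lower windows. The chromosome 13 window has no control event.

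The number of called windows depended on the scaling and on single libraries. The median log2 fold change of all tested windows was 0.78 with TMM factors and 0.22 with library totals, and with library totals the split became 23 higher and 58 lower. DESeq2 size factors in edgeR gave 85 higher and 35 lower, and distinct positions gave 26 higher and 66 lower. Without control replicate 1, 831 were higher and 8 lower, but the median log2 fold change of the 52140 windows then tested was 6.69. The fold changes as a whole were shifted upward in that fit. Without control replicate 2, 50 were higher and 10 lower. Without QKI-5 replicate 1, 2 or 3, 28, 102 and 69 were higher and 24, 89 and 43 lower, out of 892, 951 and 937 windows that then passed the filter. The median log2 fold change of the tested windows was then 0.25, 0.32 and 0.27.

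The third part located significant crosslink sites. They took 8.4, 26.2 and 34.2% of positions in controls 1, 2 and 3. In QKI-5 replicates 1, 2 and 3 the shares were 16.1, 20.6 and 23.9%. With each position counted once, the shares were 3.33, 6.68 and 4.7% in controls and 8.05, 4.9 and 4.45% in QKI-5 libraries. On both scales the QKI-5 share was the higher one only for number 1, so called sites were not particular to QKI-5 libraries. The libraries differed in depth, and these shares were not tested. The 3 QKI-5 libraries gave 67563 reproducible clusters with a median width of 12 nt (interquartile range 5 to 21), spread over 27786 windows, and 17001 clusters were found in all 3 libraries. A cluster held a median of 14 events over the QKI-5 libraries. A separate call with each position counted once gave 13689 reproducible clusters, and 13327 of the reported clusters (19.7%) lay within 15 nt of one of them. Without QKI-5 replicate 1, 2 or 3 the other libraries shared 23101, 44385 and 33594 clusters, and at a false discovery rate under 0.01 there were 42237. Thinning the QKI-5 libraries to the smallest of them left 27909.

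**Figure D3:**
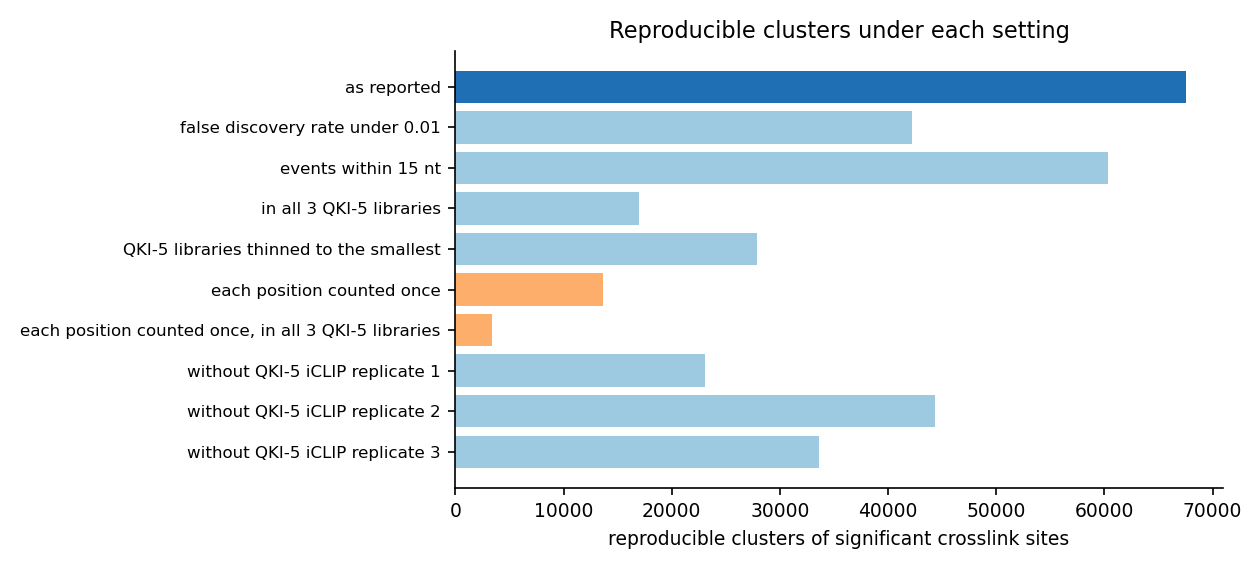
Number of reproducible clusters of significant crosslink sites as reported (dark blue), under alternatives fixed before the data were examined (light blue) and with each position counted once (orange). The count falls from 67563 as reported to 13689 with each position counted once and to 3343 when such clusters had to be found in all 3 QKI-5 libraries.

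The 8 windows with the most reproducible clusters held 31 to 45 each. Those on the plus strand of chromosome 11 formed 2 neighbouring pairs. The pair from 65190001 to 65210000 held 38 and 45 clusters, and the pair from 65260001 to 65280000 held 34 and 35. Counted once, positions in the first pair gave 8 and 7 clusters and those in the second pair gave 29 and 30. The window 65190001 to 65200000 held 2830 ± 680 EPM in QKI-5 libraries and 1436 ± 792 EPM in controls (log2 fold change 1.85, adjusted p = 0.149 by edgeR), and that log2 fold change was 1.02 with library totals, 0.06 with distinct positions and 0.97, 1.18 and 1.10 without QKI-5 replicate 1, 2 or 3. The window 65270001 to 65280000 held 2904 ± 318 against 3068 ± 302 EPM. Its log2 fold change was 0.59 with TMM factors and -0.08 with library totals, so it showed no stable direction. With distinct positions it was -1.22. In both windows the number of positions is limited by the window length, which lowers the distinct-position value for deep libraries. The other windows lay on chromosome 6 (plus strand, 37820001 to 37830000, 37 clusters), chromosome 22 (minus strand, 38880001 to 38890000, 35 clusters), chromosome 5 (minus strand, 179040001 to 179050000, 33 clusters) and the mitochondrial genome (plus strand, from 10001, 31 clusters). None of the 8 passed the window test in edgeR, at adjusted p from 0.149 to 0.911, but without control replicate 1, 6 of the 8 did, and the DESeq2 Wald test called the window from 65190001. The median log2 fold change of the tested windows was 6.69 without control replicate 1 and 0.78 with all libraries, but over different sets of windows. In the same windows the rise was smaller. It was from 1.85 to 2.42 for the window from 65190001 and from 0.59 to 1.53 for that from 65270001, and all 8 rose. Those 6 calls therefore came with higher fold changes in all 8 windows, in a fit whose scaling also changed.

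The 5 strongest reproducible clusters held more EPM in the pooled controls than in the pooled QKI-5 libraries. On chromosome 21, plus strand, 9827100 to 9827546 held 11335, 19083 and 11500 EPM in QKI-5 replicates 1, 2 and 3 and 24912, 37975 and 20866 EPM in the controls. The pooled values were 8416 against 19115 EPM on chromosome 12 (plus strand, 20704355 to 20704467) and 5892 against 21089 EPM on chromosome X (plus strand, 108297703 to 108297811). QKI-5 replicate 2 exceeded control replicate 3 in both, with 14923 against 14425 EPM on chromosome 12 and 11340 against 10634 EPM on chromosome X. The pooled values were 4734 against 21117 EPM on chromosome 2 (minus strand, 133012574 to 133012628) and 4486 against 14923 EPM on chromosome 5 (plus strand, 71146740 to 71146849). These belong to a set of 20 windows with the largest control shares, which held 18.9 ± 4.62% of control events and 8.21 ± 3.25% of QKI-5 events (SD, n = 3, two-sided exact permutation p = 0.1). All 20 had a lower mean share in QKI-5 libraries, with a median log2 ratio of -1.21 and a range from -2.65 to -0.08. In 10 of the 20 every QKI-5 share lay below every control share, an order that chance gives in 5% of windows not chosen for it. The ratio of -0.08 belongs to the window from 65270001 on chromosome 11, which showed no stable direction. The 20 were chosen for their control share, which favours that direction.

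**Figure D4:**
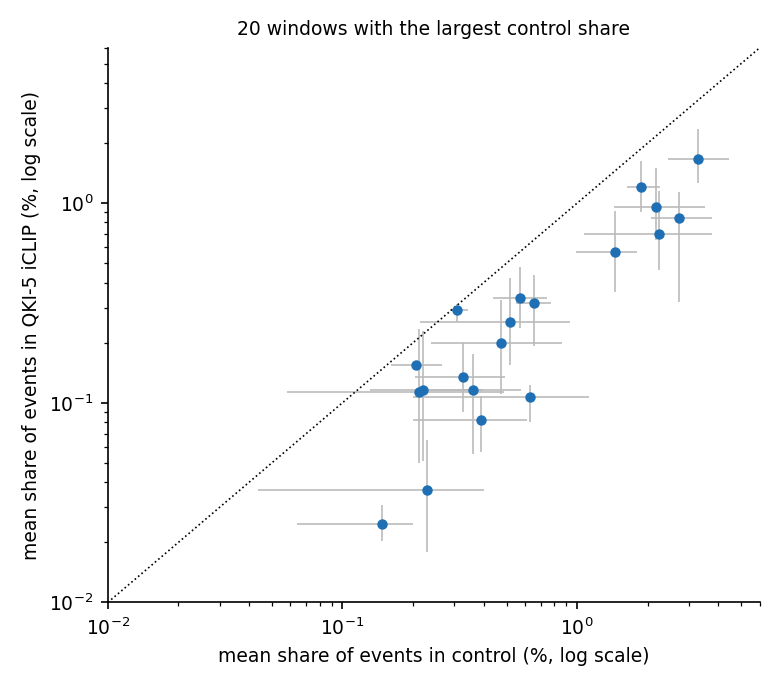
Mean share of events in QKI-5 iCLIP against control for the 20 windows with the largest control share, both on log axes in percent, with bars from the lowest to the highest of 3 libraries and a dotted line of equal shares. All 20 points lie below the line of equal shares, with a median log2 ratio of -1.21.

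Outside those windows, clusters called in 2 QKI-5 libraries were measured in the library left out and in the controls, a comparison added after the data were seen. They held 8.37 ± 1.43% of the events of the held-out QKI-5 libraries and 4.77 ± 1.10% of control events (SD, n = 3, ratio 1.75, two-sided exact permutation p = 0.1). The windows left out held 18.9% of control and 8.21% of QKI-5 events, so leaving them out favours QKI-5. Over all windows, the reproducible clusters, which were not held out, held 21.96, 27.65 and 22.31% of events in QKI-5 replicates 1, 2 and 3. Controls 1, 2 and 3 held 22.74, 29.96 and 23.13% there, so no QKI-5 excess was seen over all windows. With clusters called on positions counted once, the shares of distinct positions were 2.10 ± 1.23% and 2.41 ± 0.852% (two-sided exact permutation p = 0.7). A position counts once however many events it holds, so this scale lowers the share of deep libraries in narrow clusters. In clusters called without QKI-5 replicate 1, that library held 0.735% and controls 1, 2 and 3 held 1.17, 2.33 and 2.37%. This scale therefore cannot decide whether the difference in events holds. Of the 8 strongest clusters outside the 20 windows, a set chosen after the data were seen, 5 held more EPM in the pooled QKI-5 libraries and 3 in the pooled controls. The strongest lay on chromosome 11, plus strand, 65196032 to 65196147. It held 1436, 665 and 701 EPM in the QKI-5 libraries and 36.3, 48.2 and 503 EPM in controls 1, 2 and 3. The pooled controls held 105 EPM there, or 39.0 without control replicate 3 and 238 without control replicate 1. On chromosome 3, plus strand, 128470938 to 128471143 held 272, 209 and 202 EPM in the QKI-5 libraries and 7.25, 0 and 369 EPM in the controls, from 1, 0 and 11 events, so control replicate 3 lay above every QKI-5 library. The pooled controls held 57.4 EPM, or 5.57 without control replicate 3 and 154 without control replicate 1. On chromosome 7, minus strand, 26230915 to 26231052 held 247, 165 and 204 EPM against 0, 0 and 168 EPM, from 0, 0 and 5 events, so control replicate 3 lay above QKI-5 replicate 2 and held the only control events. On chromosome 6, minus strand, 89773317 to 89773336 held 228 EPM in the pooled QKI-5 libraries and 980 in the pooled controls. The direction of 2 other clusters rested on 1 control. On chromosome 9, minus strand, 35657774 to 35658019 held 458, 829 and 557 EPM in the QKI-5 libraries and 515, 940 and 436 in the controls, and pooled 546 against 588, or 501 without control replicate 2. On chromosome 14, minus strand, 20811367 to 20811573 held 209, 415 and 428 EPM against 116, 434 and 335, and pooled 296 against 210, or 393 without control replicate 1.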

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

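Counting each position once and combining the block with another choice were added after the data were seen. All 7 other yield ratios lay above 1, from 36.1 to 115 when libraries were left out in turn. Higher and lower windows (226 and 32) numbered 23 and 58 with library totals, 26 and 66 with distinct positions, and 10 and 14 with thinned QKI-5 libraries, where only 156 windows passed the filter. DESeq2 size factors gave 85 higher, no filter gave 6 lower, and the DESeq2 Wald test gave 431 and 150. The fit with the replicate number as a block (paired) gave 0 and 0, the block with library totals 3 and 17, and the block with distinct positions 0 and 32. Leaving out each library in turn gave 28 to 831 higher and 8 to 89 lower windows. The 831 came without control replicate 1, where the median log2 fold change of the 52140 windows then tested was 6.69. Of the windows called with library totals, 23 higher and 31 lower were shared with those reported. Reproducible clusters (67563) numbered 42237 at a false discovery rate under 0.01, 17001 in all 3 libraries, 27909 after thinning, 13689 with each position counted once and 3343 of these in all 3 libraries, and 23101 to 44385 when each library was left out. Requiring more libraries or fewer events lowers that count by construction, and the cause of the other changes was not tested. For the 24 named windows, 265 of 299 alternative fold changes kept their side of the threshold, 27 lost it, 7 gained it and no called one changed direction. In simulation 36% of windows raised 4-fold and 12.5% of those lowered to 0.25 were recovered at the depth of these libraries, and no other depth was simulated. Alternatives for transcript regions, recognition elements, hexamers, splice sites and gene lists were not run, since their results need an annotation not used here.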

Other observations

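The tests of copied reads, library depth, antibody group, diluted background, passed reads and other splits, and the bounds they were judged by, were set down after the results were seen, and the test of a limit on counts before. In windows where the other QKI-5 libraries held at least 50 events with at least 95% on one strand, 99.72 ± 0.043% of QKI-5 events and 99.72 ± 0.013% of control events lay on that strand (SD, n = 3, two-sided exact permutation p = 1). The mitochondrial genome held 1.34 ± 0.377% of QKI-5 events and 1.98 ± 0.362% of control events (two-sided exact permutation p = 0.2, adjusted 0.294 over the chromosomes). The share was lower in QKI-5 in all 3 replicate numbers (1.04 against 2.39%, 1.76 against 1.80% and 1.21 against 1.74%), and 96.2 to 98.8% of these events lay on the plus strand. Exact positions recurred between libraries. Of QKI-5 replicate 2 positions, 14.4% were also QKI-5 replicate 1 positions, against 11.7% of positions 1 nt away and 1.88% of positions 500 nt away. Most of this overlap was therefore local nearness and not a match of the exact nucleotide. The share for replicate 3 in replicate 1 was 13.1%, and 11.1, 12.2 and 13.6% of the positions of controls 1, 2 and 3 were also there, so recurrence was not particular to QKI-5 libraries. Among 17493 positions drawn from each library outside the same windows, 0.274 ± 0.103% were shared between controls, 0.0506 ± 0.0097% between QKI-5 libraries and 0.0634 ± 0.0223% between a control and a QKI-5 library. These are means over pairs that share libraries (SD, 3, 3 and 9 pairs), and they were not tested.

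The 226 higher and 32 lower windows make 258 calls. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls, the real one, and the highest of the others gave 8. Among the 4 splits that part all 3 same-numbered pairs, the highest other gave 1. With 10 splits the share cannot fall under 0.05.

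Isolated positions with more than 1 event were as common in some controls as in QKI-5 libraries. Library depth, taken as the number of events, is argued against as the only cause, whether the share would rise or fall with it. With 18372 positions drawn from each library, control replicate 3, the smallest library, stood at 1.79 times QKI-5 replicate 1, the largest. Yet each QKI-5 share lay above the control share of its number (19.4, 36.1 and 41.7% against 8.28, 24.2 and 34.7%). The draw kept the full count of each position, so events were not equalized. How many reads were sequenced per cDNA is not known, and depth in that sense was not tested. The antibody group is argued against as the whole cause, since control replicate 3 exceeded QKI-5 replicate 1 by 21.7 percentage points in all isolated positions, while the difference within each number stays open between antibody and depth. A candidate explanation is that copied reads were counted as separate events, but the test of it could not decide. Isolated positions with more than 1 event recurred in a QKI-5 library of another number about as often as those with 1 event. The median ratio was 1.05 over the 6 libraries. Yet over all positions, 13.6% of control replicate 3 positions were QKI-5 replicate 1 positions, against 11.6% of positions 1 nt away. Nearness alone can therefore hold the ratio near 1, with or without copies. Isolated positions of QKI-5 replicate 1, searched in QKI-5 replicate 2, recurred least and gave 1.51, from 0.826% against 0.547%. Copied reads stay open as an explanation.

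The 20 windows with the largest control share took a smaller part of QKI-5 events. Background RNA diluted by RNA recovered with the antibody may account for it, but the test decided nothing: of the 20 windows with the largest QKI-5 share, 17 had a lower share in QKI-5 than in control libraries, and these were the 17 already chosen by control share, while the other 3 were higher in QKI-5. A limit on counts at the hottest positions in deep libraries could also lower those shares. Inside the windows, the median ratio of replicate 1 to replicate 2 QKI-5 events was 0.812 at 41 positions with at least 1000 replicate 2 events and 1.55 at 1678 positions with 10 to 99, a quotient of 0.523, where the libraries as a whole stood at 3.40. The positions were grouped by the replicate 2 count, the divisor of the ratio, which by itself lowers the ratio at high counts. Both explanations stay open, and a dilution that differs between the 2 libraries would also give such ratios.

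Strong QKI-5 clusters also held control events: drawn down to 29810 events each, QKI-5 libraries had an event in 89.7 ± 2.41 and controls in 42.8 ± 15.3 of the 100 strongest clusters outside those windows (SD, n = 3, two-sided exact permutation p = 0.1), which were chosen in the QKI-5 libraries. In EPM the groups overlapped, at 13410, 12706 and 10861 in QKI-5 libraries and 7983, 13044 and 8688 in controls 1, 2 and 3 (two-sided exact permutation p = 0.3). Reads passed from the QKI-5 library of the same number could give such events. Control positions in these clusters were found in that library 11.1 percentage points more often than depth-matched positions of the other QKI-5 libraries were, by 3.43, 18.7 and 11.3 points for numbers 1, 2 and 3. This lies between what was set for passed reads and what was set against them, so it cannot be told apart from crosslinks at the same positions. Controls of other numbers were also found there often. Positions of controls 1, 2 and 3 were in QKI-5 replicate 1 at 97.6, 98.1 and 97.4%. In QKI-5 replicate 2 the shares were 91.2, 93.2 and 85.8%, and in QKI-5 replicate 3 they were 87.3, 91.8 and 92.3%. The 11.1 points are therefore not shown to be particular to the same number. No biological explanation was tested.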
